A study of Homo sapiens with 4 samples.

How the data were processed

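RNA sequencing was done on total RNA of HCT116 cells, an established human colorectal cancer cell line, per the labels' protocols. Cells overexpressing NCBP2 were compared with cells of the PCDH control, with 2 libraries in each group. Nothing in the labels says whether the 2 libraries of a group came from separate cultures, so the spread between them may be technical.

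The values used here are a table of 38 genes, with human Ensembl gene identifiers, symbols and descriptions. Per the file headers, the authors gave for each gene a fold change of NCBP2 over control (a linear ratio), its log2, a p-value and an adjusted p-value, an expression level in each of the 4 libraries and the mean level of each group. The deposited levels are expression signal values rounded to 0.01. The unit of this signal and its scaling are not given in the sources used here, and neither are the tool behind the fold changes and p-values and the annotation. The submitters' processing notes name Bowtie 0.12.2 and the build mm9, which is a mouse genome, whereas the deposited identifiers are human. How the reads were aligned therefore remains open. The control columns are headed EV and the overexpression columns NCBP2. Because the study has only these groups, EV was taken to be the PCDH control, and its columns were not tied to single control samples.

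The table is a selection. All 38 genes are marked significant and up by the authors, the smallest fold change is 2.01 and the largest p-value is 0.0495, so the selection followed the unadjusted p-value. Other genes, including any that were lower with NCBP2, were not analysed here. The planned exact binomial test of higher against lower genes (38 against 0, two-sided p = 7.28e-12) reflects this selection and was given no weight. Depth per library is unknown, because the levels are not counts and the table covers few genes. No counting interval or limit on a value of 0 is therefore given.

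The number of genes in the authors' adjustment was read from their values. The adjusted p-value divided by the p-value is the number of tests over the gene's rank under the Benjamini-Hochberg procedure. For NCBP2 this quotient was 17776, taken as the number of tests on the assumption that NCBP2 ranked first. A rank was assigned only where the number of tests over the gene's quotient lay within 1e-06 of a whole number and no other listed gene shared the adjusted p-value. Other adjusted p-values were taken as inherited from a gene of higher p-value, with no rank assigned. The deposited adjusted p-value was 1 for 6 genes whose p-values lay between 0.0122 and 0.0432, although a gene with a p-value of 0.0495 had 0.978. The procedure cannot give this order if these 6 genes were among those adjusted, so they were treated as not adjusted.

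Levels were compared on the log2(level + 1) scale with limma 3.58.1 in R 4.3.3, using all 38 genes, all 4 libraries and no replicate block, with Benjamini-Hochberg adjustment over the 38 genes and a threshold of 0.05. Fold changes on this scale understate the change of genes with low levels. These tests describe the spread between libraries among genes that the authors had already picked as higher on the same libraries, so they are not independent evidence of a change. An exact permutation test of 2 against 2 libraries cannot give a two-sided p under 0.333. The fit was tested on simulated levels of the 38 genes in this comparison, with 19 genes changed and 50 draws per size. Every simulated gene had the same noise SD, 0.48 on the log2 scale. Standard errors of the real genes ranged from 0.20 (TMEM132B) to 1.04 (SEMA6A-AS2). The share recovered is therefore not the power for any single gene. A log2 change of 2 was recovered for 96.0% of changed genes, and a log2 change of 1 for 23.2%, with on average 0.52 and 0.24 false calls per draw.

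Fixed before the data were examined were the comparisons, 17 gene lists with 460 distinct symbols, the rule for named genes and the first alternatives. Some histone and interferon genes were entered under both an older and a newer symbol, so list sizes count symbols. The rule named NCBP2 and LIPG first, then genes by fold, p-value or level, and allowed any gene of a table of 100 genes or fewer. The lists covered lipid droplet coat and storage, lipases, fatty acid uptake and synthesis, fatty acid oxidation, cholesterol and lipoproteins, the RNA cap and mRNA export, epithelial to mesenchymal transition, proliferation, the interferon response, inflammatory cytokines, stress responses, hypoxia and glycolysis, p53 targets, Wnt targets and intestinal epithelium, histones and small RNAs, mitochondrial transcripts, and markers of other cell types. With a selected table only the number of listed members was counted, without an enrichment test. Alternatives were another pseudocount (0.1), stricter filters on level, fold and adjusted p-value, a replicate block, and leaving out each library.

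Gene positions and types were taken from GENCODE 29 on GRCh38 by Ensembl identifier, which matched 36 of the 38 genes. They describe the genes and are not coordinates of the authors' build. Random gene sets, bootstrap intervals and exact binomial tests were computed with numpy 2.4.6 and scipy 1.17.1 in Python 3.11.15.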

Results

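Gene expression was measured by RNA sequencing in HCT116 colorectal cancer cells that overexpressed NCBP2, the small subunit of the nuclear cap-binding complex, and in cells of the PCDH vector control. Each group had 2 libraries. The data comprised 38 genes that the authors had listed as higher with NCBP2, with an expression level per library in a unit that the table does not name. Depth per library is unknown. Levels were low for most listed genes: the control mean was under 1 for 25 of the 38 genes and 7 genes were listed at 0 in both control libraries. Of the 38 genes, 21 had a protein-coding description, 9 were antisense or long noncoding RNAs, 5 were pseudogenes and 3 were readthrough transcripts of neighbouring genes.

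NCBP2 itself was examined first, as the overexpressed gene. Its level was 68.5 ± 12.9 in the control libraries and 1081 ± 20.7 in the NCBP2 libraries (SD, n = 2 each), a 15.8-fold ratio of means. NCBP2 (ENSG00000114503; GRCh38 chromosome 3, 196935402 to 196942597, minus strand) had the smallest p-value of the list, with an adjusted p of 4.92e-40 in the authors' deposited table. The fold change in the authors' deposited table was 5.24, lower than the ratio of levels. On the log2(level + 1) scale the difference was 3.97 ± 0.24 (SE), with an adjusted p of 9.62e-04 in limma over the 38 genes (0.0522 without NCBP2 library 2, with 1 library left in that group), and both NCBP2 libraries lay above both controls.

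LIPG, which encodes endothelial lipase, a secreted phospholipase acting on lipoproteins, is the gene named with NCBP2 in the study's title. Its level was 3.61 and 2.52 in the control libraries and 5.58 and 3.39 in the NCBP2 libraries. The means were 3.07 ± 0.771 and 4.49 ± 1.55 (SD, n = 2 each), a 1.46-fold ratio, and the groups overlapped because NCBP2 library 2 lay below control library 1. In the authors' deposited table LIPG had a fold change of 2.56, a p-value of 0.00109 and an adjusted p of 0.432, so it did not pass the authors' adjustment. In limma on the levels the log2 difference was 0.42 ± 0.31 (SE) with an adjusted p of 0.243, which did not pass the threshold. With 2 libraries per group this does not show that LIPG was unchanged. In simulated levels with the same noise for every gene, a log2 change of 1 was recovered for only 23.2% of changed genes. The power for LIPG itself was not estimated. LIPG (ENSG00000101670) lies on GRCh38 chromosome 18, from 49560699 to 49599182 on the plus strand, and shares no exon with another annotated gene.

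Across the list, 3 genes rose at an adjusted p under 0.05 in the authors' deposited table: NCBP2, BLOC1S5-TXNDC5 and ZBED6. The count covers listed genes only. From the adjusted p-values, BLOC1S5-TXNDC5 ranked 3 among 17776 genes adjusted, and 1 gene outside the list had a p-value at or below its own. That gene therefore also passed, in a direction that is not known here. BLOC1S5-TXNDC5, a readthrough of BLOC1S5 into TXNDC5, was listed at 0 in both controls and at 1.59 and 1.41 in the NCBP2 libraries, with an adjusted p of 4.79e-04 in the authors' deposited table. Its exons overlap those of BLOC1S5 and TXNDC5 on the same strand (GRCh38 chromosome 6, 7881522 to 8064364), so its level depends on how shared reads were assigned. ZBED6, a zinc finger transcription factor gene derived from a transposon, had levels of 1.73 and 0.76 in the control libraries and 3.14 and 3.62 in the NCBP2 libraries. Its fold change was 2.53 and its adjusted p 0.0194 in the authors' deposited table. In limma over the list its log2 difference was 1.00 ± 0.29 (SE) with an adjusted p of 0.0926, which did not pass the threshold. ZBED6 lies within ZC3H11A and shares exonic sequence with it on the same strand, which makes its level uncertain too.

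The other 35 genes did not pass at this threshold, including 6 with an adjusted p entered as 1, which were treated as not adjusted. The smallest adjusted p-values among them in the authors' deposited table were 0.0707 for LRP1B, a large LDL receptor family member, 0.135 for GRIN2B, an NMDA receptor subunit, and 0.192 for the pseudogene RHOXF1P3. LRP1B levels were 0.385 ± 0.0495 and 1.00 ± 0.0849, and GRIN2B levels were 0.67 ± 0.410 and 1.62 ± 0.219, in control and NCBP2 libraries (SD, n = 2 each). From the adjusted p-values, LRP1B ranked 16 and GRIN2B ranked 22 among 17776 genes adjusted. Of these, 12 and 17 genes outside the list had p-values at or below theirs. The long noncoding RNA LINC01967 ranked 98 at a p-value of 0.0049, where a uniform distribution of p-values over 17776 genes would place 87.1 genes. At the smaller p-value of LRP1B, the observed 16 genes compared with 1.13 under a uniform distribution.

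When the spread between libraries was examined in the levels, 33 of the 38 genes had both NCBP2 libraries above both control libraries. Chance gives this order in 16.7% of unselected genes, and these genes had been selected as higher on the same libraries. The 5 genes that did not separate were LIPG, BPTFP1, ZNF587, CARF and IDI2-AS1. In limma over the list, 5 genes passed an adjusted p of 0.05, all higher: NCBP2, BLOC1S5-TXNDC5, H4C11, LINC01967 and RDH5, while 20 had an unadjusted p under 0.05. The number past the threshold changed when single libraries were left out. Such fits take their spread only from the group that keeps 2 libraries, so their counts are not comparable with the 5. For the 7 genes at 0 in both controls, among them H4C11 and BLOC1S5-TXNDC5, the controls add no spread in any fit. NCBP2 itself did not pass without NCBP2 library 2 (adjusted p of 0.0522 in limma). Control library 2 was listed below control library 1 in 28 of the 30 genes in which they differed, so the size of most differences depends on which control is used.

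Among genes with a protein-coding description, RDH5, a retinol dehydrogenase, had levels of 2.43 ± 0.0919 in the control and 7.31 ± 1.75 in the NCBP2 libraries (SD, n = 2 each), a 3.01-fold ratio with an adjusted p of 0.0353 in limma over the list. In the authors' deposited table RDH5 had a fold change of 2.11 and a p-value of 0.0107, and it did not pass the authors' adjustment. Because the list was selected on the same libraries, passing in limma is not independent evidence of a change. RDH5 shares exons with the BLOC1S1-RDH5 readthrough. H4C11, a replication-dependent histone H4 gene, was listed at 0 in both controls and at 2.95 and 5.17 in the NCBP2 libraries, with an adjusted p of 0.0141 in limma, and it belongs to a family of near-identical coding sequences, so its reads are hard to assign. In the authors' deposited table its p-value was 0.0122 with an adjusted p-value entered as 1. The following genes passed neither the authors' adjustment nor limma. The levels of HMCN1, an extracellular matrix protein of the fibulin family, were 0.51 ± 0.113 and 1.82 ± 0.46, those of FBN1, the microfibril component fibrillin 1, 0.625 ± 0.417 and 1.62 ± 0.622, and those of ITGB8, an integrin beta subunit, 0.47 ± 0.255 and 1.01 ± 0.0849, in control and NCBP2 libraries (SD, n = 2 each). ADGRV1, a very large adhesion receptor, had levels of 1.87 ± 0.424 and 3.46 ± 0.17. GLCCI1, a glucocorticoid-induced transcript, had levels of 0.93 ± 0.636 and 2.66 ± 0.141. GJA1, the gap junction protein of many tissues, was listed at 0.03 and 0 in the controls and at 0.16 and 0.53 with NCBP2, and PTHLH, parathyroid hormone-related protein, had levels of 0.45 ± 0.255 and 0.985 ± 0.00707. For NEB, the giant muscle protein nebulin, the difference rested largely on NCBP2 library 2, with levels of 2.05 and 12.13 against 1.30 and 0.30 in the controls.

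Among antisense and long noncoding RNAs, only LINC01967 passed the limma threshold over the list, which was selected on the same libraries. It had levels of 0.235 ± 0.205 in the control and 2.62 ± 0.17 in the NCBP2 libraries (SD, n = 2 each), an 11.1-fold ratio with an adjusted p of 0.0165 in limma over the list and 0.888 in the authors' deposited table. LINC02458 was the noncoding RNA with the highest mean level, 3.23 ± 1.60 in the control and 7.68 ± 2.16 with NCBP2, and its adjusted p was 0.504 in the authors' deposited table. SEMA6A-AS2 was listed at 0 in both controls and at 0.55 and 12.24 in the NCBP2 libraries, a spread between replicates larger than their mean. The pseudogene BPTFP1 was listed at 5.17 in NCBP2 library 1 and at 0 in the other 3 libraries. Of the 36 genes with a GENCODE 29 entry, 10 share exonic sequence with another gene on the same strand and 14 more only on the opposite strand. Whether reads were counted by strand is not given in the sources used here. Levels of antisense genes such as KANSL1-AS1, CCNT2-AS1 and IDI2-AS1 may therefore include reads of their partners, to an extent that cannot be told.

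**Figure D1:**
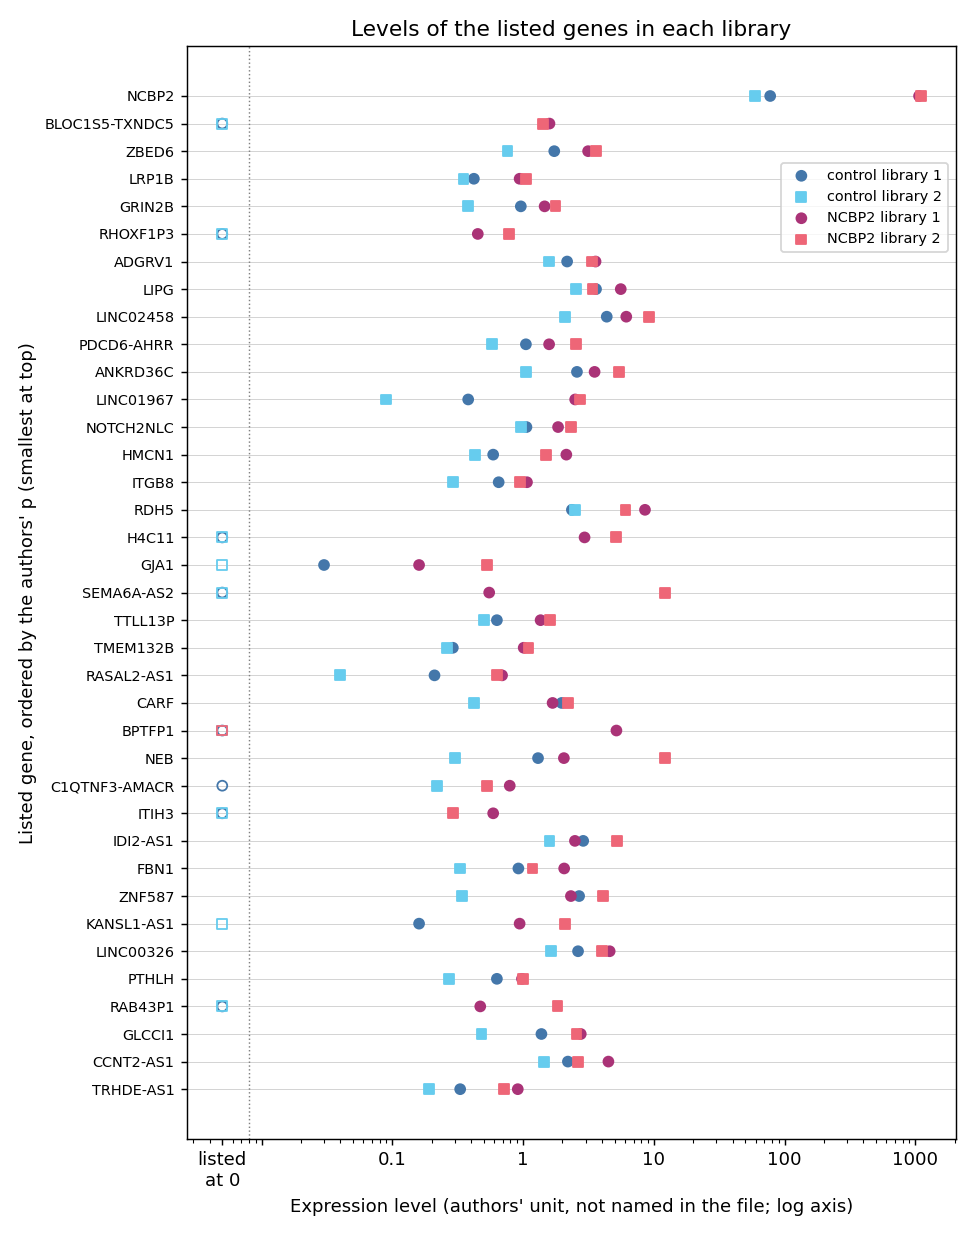
Expression level of 37 of the 38 listed genes in each of the 4 libraries, on a log axis in the authors' unnamed unit, with genes ordered by the authors' p-value. Open symbols at the left mark values listed at 0, where symbols overlap, and 1 gene on the Y chromosome is not drawn; NCBP2 stands alone near 1081 with NCBP2 overexpression, and the 2 groups overlap for LIPG.

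The lists of lipid and other genes fixed beforehand were then compared with the table. The study's title concerns lipid droplets, and the 5 lipid lists together held 138 genes. LIPG was the only one of them in the table, as 1 of 21 lipases and lipid breakdown genes. No member was listed among 32 lipid droplet coat and storage genes, such as the perilipins and DGAT enzymes, 36 fatty acid uptake and synthesis genes, 20 fatty acid oxidation genes or 29 cholesterol and lipoprotein genes. NCBP2 was the only listed member of the 20 RNA cap and mRNA export genes. The remaining lists had no listed member: epithelial to mesenchymal transition (32 genes), proliferation (33), interferon response (51), inflammatory cytokines (27), stress responses (33), hypoxia and glycolysis (20), p53 targets (19), Wnt targets and intestinal epithelium (29), histones and small RNAs (28), mitochondrial transcripts (15) and markers of other cell types (20). H4C11 is a histone gene but was not on the fixed histone list. The sizes of the histone and interferon lists count symbols, since some genes were entered under both an older and a newer symbol. Absence from the table means only that a gene was not among these 38; its level and p-value were not analysed here. For the lists fixed beforehand, a count adjusted over the members of each list alone was therefore not computed.

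The authors' fold changes were also set against the ratios of group mean levels for the 31 genes with a control level above 0. The fold in the authors' deposited table was higher than the ratio of levels for 13 genes and lower for 18, with a median log2 difference of 0.04. The values differed by more than 1.5 times in 7 genes, where the first value of each pair is from the authors' deposited table. The ratio of levels was higher for the pseudogene TXLNGY (13.3 against 49.0), NEB (2.49 against 8.86), NCBP2 (5.24 against 15.8), TMEM132B (2.12 against 3.84) and HMCN1 (2.13 against 3.56), and lower for PTHLH (4.82 against 2.19) and LIPG (2.56 against 1.46). TXLNGY was listed at 0.01 in both controls, the rounding step of the levels, so its ratio is uncertain. The ratio of NEB rested largely on NCBP2 library 2 (12.13, against 2.05 in NCBP2 library 1). By the ratio of levels, 26 of the 31 genes were at least 2-fold higher and 5 genes, LIPG, CARF, IDI2-AS1, ADGRV1 and CCNT2-AS1, were below 2-fold.

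**Figure D2:**
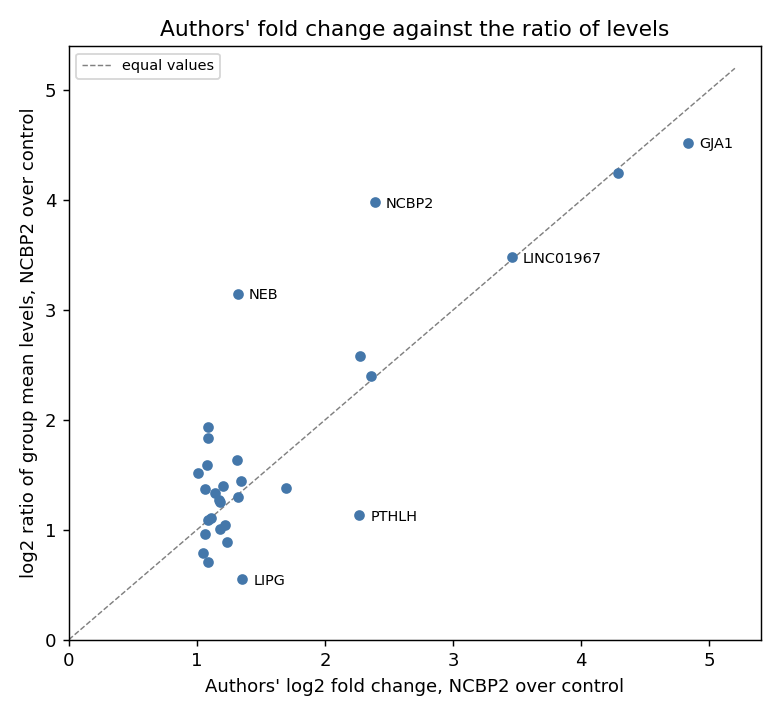
Log2 ratio of group mean levels (vertical axis) against the authors' log2 fold change (horizontal axis), NCBP2 over control, for 30 genes with a control level above 0; each point is a gene, the dashed line marks equal values and TXLNGY, on the Y chromosome, is not drawn. NCBP2 and NEB lie above the line, and PTHLH and LIPG below it.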

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

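The number of listed genes past the limma threshold (5, all higher) moved with most settings: it was 14 with a pseudocount of 0.1, all 5 original genes included, and between 1 and 12 when single libraries were left out, the extremes being 1 without control library 1 or 2 and 12 without NCBP2 library 1. With the number in the column headings as a replicate block it was 1. That fit had 1 residual degree of freedom against 2 without the block, so its count is not comparable with the 5. The number was 3 among the 24 genes with a mean level of at least 1. Without NCBP2 in the fit it was 4. Of the 38 genes in the authors' table, 15 had a log2 fold of at least 2, 3 had an adjusted p under 0.05, 2 had one under 0.01, the same number as under 0.001, and 19 had a mean level at or above the list's median. The log2 difference of NCBP2 stayed between 3.78 and 4.16 when single libraries were left out. Its adjusted p in limma was between 0.00673 and 0.0522, above 0.05 only without NCBP2 library 2. The difference of LIPG lay between 0.12 (without NCBP2 library 1) and 0.71 (without NCBP2 library 2), and its adjusted p between 0.184 and 0.734 over all alternatives, so it passed the threshold in none. The groups were separate for 33 of 38 genes, for 33 to 37 when a library was left out (which can only keep or raise this count and so says nothing of stability), and for 19 of the 24 genes with a mean level of at least 1. With 1 library left in a group, that library was assumed to vary like the others. The deviations of same-numbered libraries had a correlation of -0.17 across the listed genes. These genes were selected on the same libraries, and the control columns were not tied to single samples. Whether same-numbered libraries were paired therefore cannot be told. The filter at a mean level of 5 left 2 genes and was not fitted, no filter is the same as the setting used, and set tests and count-based tools were not run because the table holds neither all genes nor counts. The filter at a mean level of 1, the fit without NCBP2, the adjusted p limit of 0.05 and the changes to the separation count were chosen after seeing the data. The cause of these changes was not tested. Depth is unknown, so which low levels rest on few reads cannot be said.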

Other observations

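The tests of the NCBP2 fold by a common scaling, of the control libraries and of the genomic span of the listed genes were chosen only after the values, or the gene positions, had been seen. The tests on NCBP2 transcript length and on sets matched for exonic length were set before those lengths were looked up.

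The listed protein-coding genes include several with long genomic spans: LRP1B spans 1900279 bp, ADGRV1 635094 bp, GRIN2B 544016 bp, TMEM132B 475542 bp and HMCN1 456399 bp in GENCODE 29. For the 23 protein-coding genes with a GENCODE entry, the median span was 85.1 kb against 27.1 kb for all 19951 protein-coding genes (one-sided permutation p = 0.00093 for the median over 100000 random sets, which restates what prompted the test and is no independent evidence). Spans exceeded 100 kb in 11 of the 23 (47.8%), against 18.0% of all protein-coding genes. The 11 include the readthroughs BLOC1S5-TXNDC5 (182843 bp) and C1QTNF3-AMACR (137355 bp), which span neighbouring genes. The 23 also include TTLL13P, a pseudogene by its description. The tests were not repeated without these genes. The exonic sequence of the 23 genes was long as well, with a median of 8574 bp against 4215 bp. Against random sets matched on exonic length the median expected span was 58.9 kb and the excess was no longer past the threshold (one-sided permutation p = 0.118), so long exonic sequence may account for much of it. The background was all annotated protein-coding genes, not the genes the authors tested, so differences between expressed and silent genes stay open, as does a biological effect of NCBP2 on long transcripts, which was not tested.

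Control library 2 was listed below control library 1 in 28 genes and above it in 2, while the NCBP2 libraries split 15 against 23 (exact two-sided binomial p = 0.256). Selection of genes with chance low values in the controls would make either control the lower one about equally often if genes varied independently. The exact two-sided binomial p of the split, 8.68e-07, is computed on the values that prompted it and on genes of a single pair of libraries, which are not independent, so selection stays open. A single scaling factor between the control libraries stays open too: NCBP2, the gene with the highest level, had a log2 ratio of library 1 to 2 of 0.39, and the 12 other genes with a control mean of at least 1 had a median of 0.77 with an interquartile range of 0.51 to 1.21. The value of NCBP2 lay below that range, which a single factor alone predicted would include it, but selection of genes with low control values could have raised the other ratios. A difference in RNA or library quality between the controls cannot be told apart from it with 38 genes. The controls were listed at equal values in the other 8 genes.

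The ratio of levels of NCBP2 was 3.02 times the authors' fold. A scaling difference common to the genes predicts a like offset in the others, but their median offset was 0.029 on the log2 scale (95% bootstrap interval -0.07 to 0.19, 30 genes), against 1.59 for NCBP2, which argues against that explanation. Larger offsets were computed for TXLNGY (1.88) and NEB (1.83), but neither is secure. TXLNGY was listed at 0.01 in both controls, which is the rounding step of the levels. The NEB ratio rested largely on NCBP2 library 2 (12.13, against 2.05 in NCBP2 library 1). For NCBP2 only, a candidate explanation is that levels were divided by transcript length and that reads from a coding-region construct were assigned to a short transcript. The longest NCBP2 transcript with the main coding region has 2169 nt and the coding region 468 nt, a quotient of 4.63. The observed 3.02 lay outside the range set in advance around that quotient, 3.71 to 5.79. That quotient divides by the coding region, whereas the shortest annotated NCBP2 transcript has 548 nt. The range therefore does not cover assignment to a short annotated transcript, and the miss decides nothing. The bound that would have argued against the explanation was 8.89, and it was not exceeded either. It divides the longest annotated transcript, of the retained intron type, by the coding region, so it was hard to exceed. The explanation stays open. Its construct part could not apply to TXLNGY or NEB. Whether the assignment of reads to transcripts shaped their ratios was not tested. Whether the construct held only the coding region is not given in the sources used here, and levels per transcript were not analysed here.

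LIPG was listed on its unadjusted p-value. At the p-value of LINC02458, the next gene in the list, the authors' adjusted p was already 0.504.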
